A study of Bursaphelenchus xylophilus with 12 samples.

How the data were processed

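Messenger RNA of adult Bursaphelenchus xylophilus was sequenced in 12 libraries, 3 for each of the groups EB12, EC12, EB24 and EC24. Groups and replicate numbers were taken from the library titles. The 12 h titles also carry a group number, which differs between EB12 and EC12 and which the 24 h titles lack. The treatment text in the labels calls the adjuvant groups ON, while the titles say EC, and the match was made by elimination. Per the labels, worms were fed on the fungus Botrytis cinerea and immersed at 25 °C. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

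The authors deposited 1 table of FPKM values with 2 decimals for 18036 IDs, of which 17704 start with BXY and 332 with XLOC. TopHat2 2.1.1 is named in the submitters' processing notes. The genome build, the annotation, the counting tool, strand handling and any filter on genes are not given in the sources used here. All 12 value columns matched 1 library title each. No pair of libraries was identical. FPKM is scaled to the library, so a change in a few abundant genes shifts all others, and reads shared between near-identical or overlapping genes cannot be told apart.

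From these values log2(FPKM + 1) was computed for the 13768 IDs (13553 BXY and 215 XLOC) with an FPKM of at least 1 in at least 3 libraries. Fold changes are on this scale, which understates the change of low genes. A linear model with 1 mean per group was fitted over all 12 libraries with limma 3.58.1 in R 4.3.3, with moderated variances that follow the mean (eBayes with trend), and contrasts were tested two-sided with Benjamini-Hochberg adjustment over all tested genes at 0.05. One estimate of the spread per gene was therefore shared by both times. No count model was used, since the values are not counts.

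The fit was tested on simulated data with the genes' observed means, their own SD at each time, and 100 genes changed by 1 and 100 by 2 log2 units per comparison, among 13768 genes. The simulated noise was independent between genes. For EB12 against EC12 it recovered 71% of changes of 1 log2 unit and 97% of changes of 2, but called 197 unchanged genes, against 32%, 76% and 5 when the 6 libraries were fitted alone. For EB24 against EC24 it recovered 65% and 92% and called 4 unchanged genes, against 79%, 98% and 5.

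The named genes are, per comparison of agents, the 2 largest rises and the 2 largest falls among called genes with a mean FPKM of at least 1 and no overlap between the groups. For the interaction they are, among the 4 smallest adjusted p-values, at most 2 of each sign. Genes are given by ID because the table does not pair IDs with names. This rule, the design and most alternatives were fixed before the data were examined. The 34 gene lists fixed at the same time (detoxification enzymes, ion channels, proteases, cuticle, sperm and yolk markers and others) need gene descriptions or protein sequences, which were not used here, so 0 lists were filled and no list was tested.

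Step depth was estimated from genes with low FPKM: the ratio of the values of 2 libraries clusters at ratios of small whole numbers times the ratio of their depths, and the best and second-best fits were recorded, which differ by a factor of 2. The counting behind high values was not recovered, so no interval that needs a read count is given. The replicate numbers were not in the model. Alternatives were pseudocounts of 0.1 and 0.5, no filter, a mean FPKM of at least 5, median ratio scaling, quantile normalization, fits of the compared groups alone, a replicate block, no trend, weights per library or per time, a log2 change of at least 1, and leaving out each library. Regroupings of the libraries numbered 10 per pair of groups and 100 for the interaction, with all 20 regroupings of the 12 h libraries that keep the 24 h groups added after seeing the data.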

Results

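Adult pine wood nematodes (Bursaphelenchus xylophilus, the nematode of pine wilt disease, strain NB-6) were immersed in emamectin benzoate (EB) at 0.1 mg/L or in the matching adjuvant for 12 h or 24 h, and their messenger RNA was sequenced. Emamectin benzoate belongs to the avermectins, which act on glutamate-gated chloride channels of invertebrates. The 12 libraries, each from 200 adults, form 4 groups of 3: EB12, EC12, EB24 and EC24, the number being the hours of exposure. The labels do not spell out EC. The design text names EB and adjuvant only, so the EC libraries were taken as the adjuvant controls by elimination. The table listed FPKM (fragments per kilobase of gene, scaled to the size of the library) for 18036 gene IDs. The IDs came without symbols or descriptions, so that the pathways and cell types behind the changes are not analysed here, and genes are given by ID.

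The FPKM values summed to 865643 ± 4773 (SD, n = 3) in EB12, 831384 ± 12335 in EC12, 924230 ± 6672 in EB24 and 939269 ± 6264 in EC24. Between 12543 and 13358 IDs per library stood at an FPKM of at least 1, and between 2333 and 2761 stood at 0. Read totals are unknown. The steps between low values gave the depth of each library relative to EC24 replicate 1, which was 1 to 1.66 among the 24 h libraries. For the 12 h libraries the best reading was 1.16 to 2.46. The next-best readings differed by a factor of 2, and the lower reading of each 12 h library was 0.986 to 1.23. The log-likelihood gap between the readings was 7.67 for EC12 replicate 1, 52.3 to 227 for the other 12 h libraries and 166 to 398 at 24 h.

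The libraries separated first by time. Principal component 1 held 55.1% of the variance of log2(FPKM + 1) over the 13768 tested genes and placed all 6 libraries at 12 h on one side and all 6 at 24 h on the other. At 24 h the agents separated cleanly, with Pearson correlations across genes of 0.991 to 0.994 within a group and of 0.966 to 0.968 between EB24 and EC24. At 12 h they did not: the correlations were 0.943 to 0.976 within a group and 0.938 to 0.980 between EB12 and EC12. The median SD of a gene between replicates was 0.26 log2 units in both EB12 and EC12, 0.09 in EB24 and 0.12 in EC24. On component 2, EB12 replicates 1 and 3 and EC12 replicate 1 lay at -42.6, -18.2 and -18.8, and EB12 replicate 2 and EC12 replicates 2 and 3 at 27.9, 7.41 and 29.9.

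**Figure D1:**
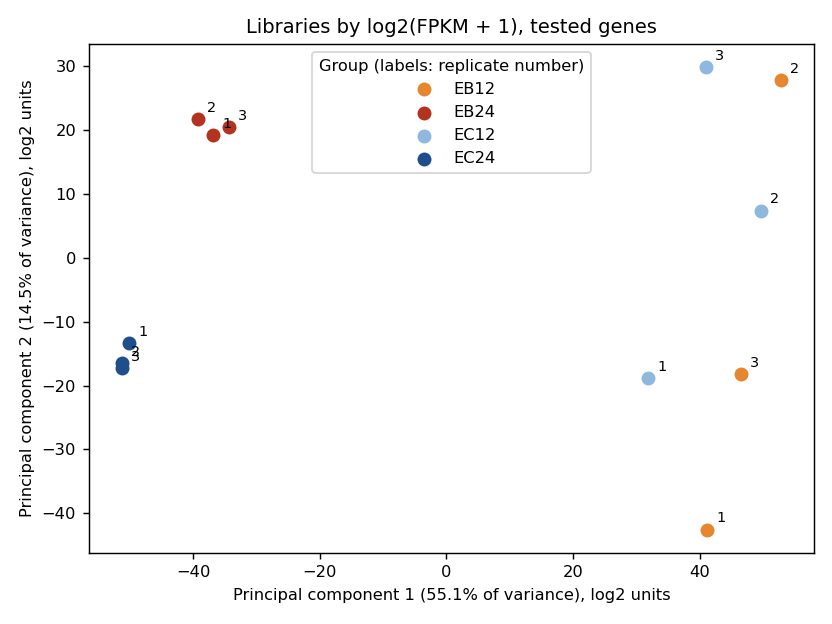
Principal components 1 (55.1% of the variance, x axis) and 2 (14.5%, y axis) of log2(FPKM + 1), in log2 units, with 1 point per library coloured by group and numbered by replicate. The 24 h groups form tight, separate clusters, while the EB12 and EC12 libraries are spread along component 2 and intermix.

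The comparison of EB24 with EC24 asks how the worms differed after 24 h in EB. Of the 13768 genes tested, 1998 were higher and 653 lower with EB (limma, Benjamini-Hochberg adjusted p under 0.05), and 307 were higher and 195 lower by at least 2-fold on the log2(FPKM + 1) scale. BXY_0356800 had the largest positive difference, with 7.32 ± 0.541 FPKM in EC24 and 65.7 ± 2.08 in EB24 (SD, n = 3), a log2 difference of 3.00 ± 0.49 (SE; limma adjusted p = 0.0029). EB24 lay below both 12 h means of this gene, 253 ± 152 FPKM in EC12 and 109 ± 85.8 in EB12, and the gene fell from EC12 to EC24 (log2 difference -4.78, limma adjusted p = 2.3e-05). BXY_0182200 stood at 10.3 ± 1.42 FPKM in EC24 and 64.4 ± 1.47 in EB24, a log2 difference of 2.54 ± 0.39 (limma adjusted p = 0.00218). Among genes lower with EB, BXY_1484600 stood at 261 ± 16.5 FPKM in EC24 and 8.43 ± 1.52 in EB24, a log2 difference of -4.81 ± 1.18 (limma adjusted p = 0.0176). BXY_0827600 stood at 75.8 ± 4.94 FPKM in EC24 and 2.07 ± 0.501 in EB24, a log2 difference of -4.65 ± 1.09 (limma adjusted p = 0.0149). These 2 lower genes had means of 25.7 ± 21.9 and 16.4 ± 13.8 FPKM in EC12 and 45.8 ± 72.1 and 30.2 ± 48.2 in EB12, with 129 and 85.9 FPKM in EB12 replicate 2 and 1.33 and 1.02 in EB12 replicate 3. Without any 1 of the 6 libraries at 24 h the log2 differences stayed at -4.69 to -4.92 and -4.56 to -4.78. The limma adjusted p of BXY_1484600 then rose to 0.0515 to 0.0608, and that of BXY_0827600 to 0.0509 without EB24 replicate 1, 0.0536 without EB24 replicate 2 and 0.0515 without EC24 replicate 3. In the 24 h libraries alone the limma adjusted p was 5.19e-08 and 6e-08, and at most 2.78e-06 with any 1 library left out.

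Changes at 24 h covered every level of abundance, in classes of unequal size. As deposited, 6.46% of the 3221 genes with a mean FPKM under 5 were higher and 3.01% lower. The shares were 10.5% and 4.01% of 3590 genes at 5 to 20, and 17.9% and 4.57% of 3063 at 20 to 50. They were 23.7% and 5.59% of 3131 genes at 50 to 200, and 16.1% and 12.7% of 763 at 200 or more. Higher calls outnumbered lower ones with all 3 scalings among genes with a mean FPKM of 50 to 200 (742 and 175 as deposited, 399 and 226 after median ratio scaling, 464 and 254 after quantile normalization) and of 20 to 50 (547 and 140, 294 and 189, 333 and 305). The direction flipped after quantile normalization for a mean of 5 to 20 (378 and 144, 185 and 174, 276 and 306) and under 5 (208 and 97, 114 and 97, 141 and 162). It flipped after median ratio scaling for a mean of 200 or more (123 and 97, 85 and 112, 131 and 52). Of the 100 most abundant genes, 6 were higher, 16 lower and 78 did not pass the test, with a median log2 difference of -0.19. The same 100 genes gave 4 higher and 17 lower calls after median ratio scaling, with a median of -0.28, but 11 higher and 4 lower calls after quantile normalization, with a median of 0.02.

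The excess of higher calls at 24 h also moved with the scaling. It was 75.4% of calls with the FPKM as deposited, when the median of all genes stood at 0.14 log2 units. It was 57.4% after rescaling by the median ratio (1077 higher, 798 lower; median 0.06) and 55.5% after quantile normalization (1345 higher, 1079 lower; median 0.03). With the 24 h libraries alone, whose spread was smaller, the test called 7267 genes (4941 higher, 2326 lower), and all 2651 calls of the 12-library fit were among them with the same sign. The 12-library count was 1207, 980 and 1073 without EB24 replicates 1, 2 and 3, and 1361, 1160 and 1127 without EC24 replicates 1, 2 and 3, against 6080 to 7453 when the 24 h libraries were fitted alone.

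**Figure D2:**
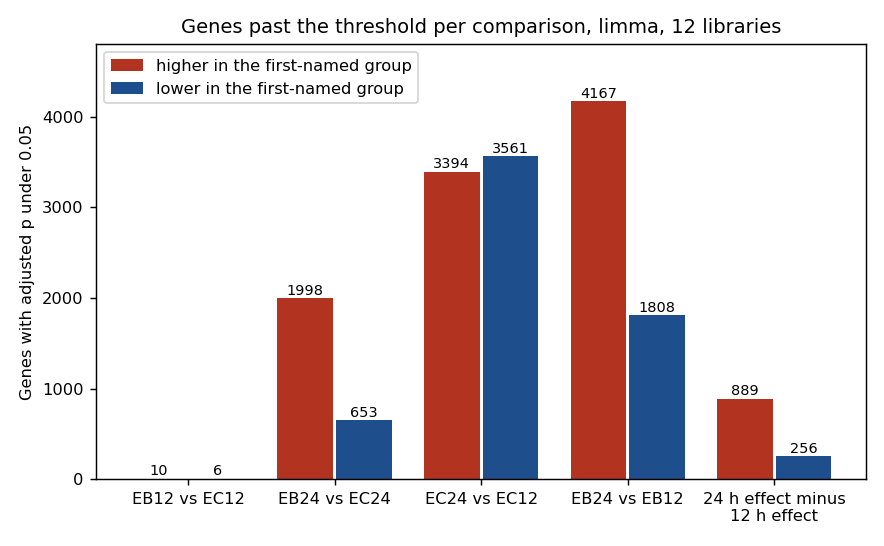
Number of genes (y axis) with a limma adjusted p under 0.05 in each comparison (x axis), split into genes higher (red) and lower (blue) in the first-named group, or with a positive or negative difference between the 24 h and the 12 h effect. The 12 h comparison of agents holds 16 genes and the 24 h comparison 2651.

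The comparison of EB12 with EC12 asks for changes after 12 h. It called 16 genes, 10 higher and 6 lower with EB. BXY_0293300 stood at 5.36 ± 1.07 FPKM in EC12 and 27.8 ± 9.09 in EB12 (SD, n = 3), a log2 difference of 2.15 ± 0.21 (SE; limma adjusted p = 0.00196). BXY_1144700 stood at 18.03 ± 4.74 FPKM in EC12 and 75.3 ± 25.1 in EB12, a log2 difference of 1.97 ± 0.25 (limma adjusted p = 0.0155). At 24 h their log2 differences were -0.38 and 0.02 (limma adjusted p = 0.218 and 0.962). In the other direction, BXY_0200700 stood at 36.4 ± 11.3 FPKM in EC12 and 13.5 ± 1.87 in EB12 (log2 difference -1.33 ± 0.19, limma adjusted p = 0.0282). BXY_0984700 stood at 21.2 ± 1.25 and 10.04 ± 1.80 FPKM (log2 difference -1.02 ± 0.14, limma adjusted p = 0.021). For these lower genes the log2 differences at 24 h were -0.52 and -0.27 (limma adjusted p = 0.0799 and 0.185).

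None of these 16 calls held against the spread of the 12 h libraries alone. With weights per time point 2 held, but that fit still includes the 24 h libraries in the spread. Fitted alone, the 6 libraries at 12 h gave 0 calls in limma, the smallest adjusted p being 0.392, with 566 genes at an unadjusted p under 0.05 against 688 expected by chance, and the 4 named genes had adjusted p of 0.415, 0.497, 0.979 and 0.979 there. The 2 groups did not overlap for 9.83% of genes, where chance gives 10%, against 60.1% at 24 h. In simulated data with the observed spreads, the 12-library fit called 197 unchanged genes at 12 h and 4 at 24 h, of 13768 genes simulated. There the fit of the 6 libraries at 12 h recovered 32% of changes of 1 log2 unit and 76% of changes of 2. The simulated noise was independent between genes, while 1 axis held 54.7% of the real variance within the 12 h groups. The 197 is therefore no count of false calls among the real libraries. The count also moved with single libraries: it was 310 without EB12 replicate 2, 79 without EC12 replicate 2, 34 without EB12 replicate 1, 25 without EC12 replicate 1, 8 without EC12 replicate 3 and 4 without EB12 replicate 3. Without EB12 replicate 3 the log2 difference was 1.84 for BXY_1144700 (limma adjusted p = 0.082) and -1.24 for BXY_0200700 (limma adjusted p = 0.0991), and without EC12 replicate 3 it was -0.99 for BXY_0984700 (limma adjusted p = 0.0758). BXY_0293300 stayed called without any 1 library at 12 h (limma adjusted p of 0.00145 to 0.0139) and with weights per time point (limma adjusted p = 0.0148).

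**Figure D3:**
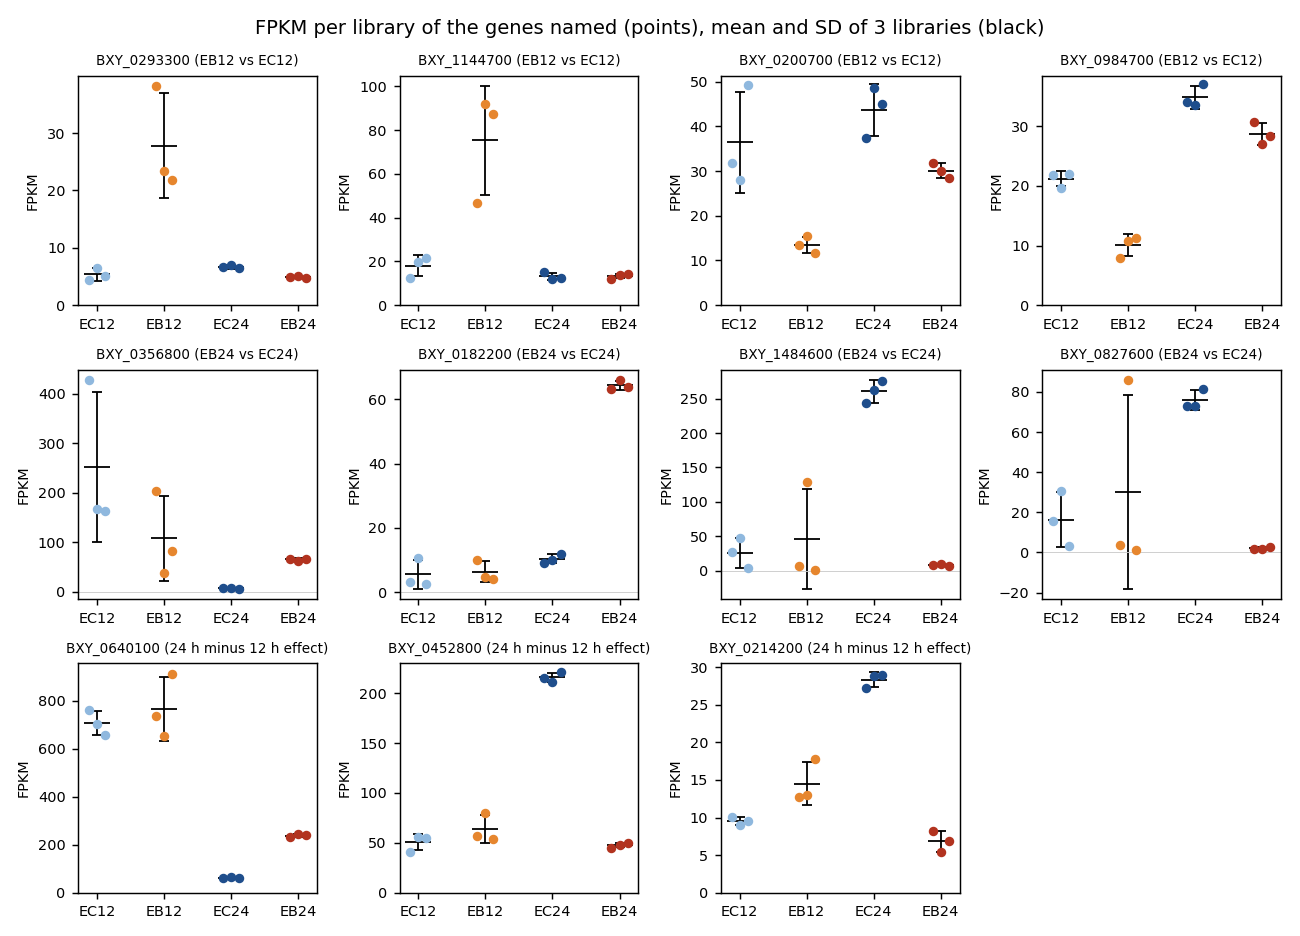
FPKM (y axis, linear) in each of the 12 libraries for the 11 genes named, 1 panel per gene with the comparison it was chosen for, with groups on the x axis, points for libraries, and black bars for the mean and SD of 3 libraries. The 3 points of each 24 h group lie close together, while those of BXY_1484600 and BXY_0827600 at 12 h span from near 1 to above 80 FPKM; lower SD bars can extend below 0.

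The calls at 12 h and 24 h were compared by direction. Both lists use the same SE per gene from the 12-library fit, which can raise their overlap above that of independent lists. Of the 10 genes higher at 12 h, 3 were also higher at 24 h, where independent lists would share 1.45 (Fisher's exact test, two-sided, p = 0.167). Of the 6 lower genes, 1 was also lower at 24 h, against 0.285 for independent lists (Fisher's exact test, two-sided, p = 0.253). In opposite directions, 1 gene was higher at 12 h and lower at 24 h, against 0.474, and 1 lower and then higher, against 0.871 (Fisher's exact tests, two-sided, p = 0.385 and 1). The log2 differences at the 2 times, which share no library, correlated across genes at r = -0.11 (Spearman -0.04), and genes are not independent replicates. The 4 genes shared in direction became 51 without EB12 replicate 2, 24 without EC12 replicate 2, 7 without EB12 replicate 1 or EC12 replicate 1, 1 without EB12 replicate 3, and 2 without any 1 EB24 replicate or EC24 replicate 2 or 3.

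The difference between the agent effects was tested as an interaction. It passed the threshold for 1145 genes (limma adjusted p under 0.05), with 889 more positive and 256 more negative at 24 h. With the 24 h groups kept, 8 of the 20 ways to regroup the 12 h libraries, the real one included, gave at least as many genes. Of the 1145, 954 were also called in the 24 h comparison with that sign and 11 in the 12 h comparison, and 182 in neither. In 977 of the 1145 the estimates at 12 h and 24 h had opposite signs. Selection on the difference between the estimates favours opposite signs, and the 12 h libraries fitted alone gave 0 calls. BXY_0640100 stood at 708 ± 51.5 FPKM in EC12 and 767 ± 133 in EB12, and at 61.9 ± 1.73 in EC24 and 239 ± 6.07 in EB24 (SD, n = 3). Its effect was 1.83 ± 0.16 log2 units higher at 24 h (SE; limma adjusted p = 0.000953). BXY_0452800 stood at 50.6 ± 8.11 FPKM in EC12, 63.6 ± 13.96 in EB12, 216 ± 4.76 in EC24 and 47.7 ± 2.22 in EB24 (interaction of -2.47 ± 0.21, limma adjusted p = 0.000953). BXY_0214200 followed the same order, with 9.54 ± 0.530, 14.5 ± 2.83, 28.3 ± 0.978 and 6.85 ± 1.37 FPKM (interaction of -2.46 ± 0.24, limma adjusted p = 0.00129). The count depended on the scaling, with 520 genes after rescaling by the median ratio, of which 45.6% were positive, against 77.6% as deposited and 56.1% after quantile normalization, while the median interaction of all genes went from 0.21 to 0.07 with either scaling. It was 2466 without EB12 replicate 2, 1828 without EC12 replicate 1, 723 without EC12 replicate 3, 458 without EB12 replicate 3, 223, 197 and 177 without EB24 replicates 1, 2 and 3, and 382, 198 and 180 without EC24 replicates 1, 2 and 3.

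The comparisons over time ask what changed from 12 h to 24 h within each agent. In the EC libraries 3394 genes rose and 3561 fell, and in the EB libraries 4167 rose and 1808 fell (limma adjusted p under 0.05). The share of rising genes in EB was 69.7% as deposited, 56.4% after median ratio scaling and 50.3% after quantile normalization, and the median of all genes was 0.15, 0.03 and -0.02 log2 units. In EC it was 48.8%, 50.5% and 45.7%. Rising genes shared between the agents numbered 2390, against 1027 for independent lists, and falling genes 1418, against 468. Both lists use the same SE per gene from the 12-library fit, which can raise their overlap above that of independent lists. Opposite calls were found for 21 genes that rose in EC and fell in EB and for 62 that fell in EC and rose in EB. The 2 changes, which share no library, correlated across genes at r = 0.70 (Spearman 0.71). Of the 100 most abundant genes, 62 rose and 8 fell in EC, and 29 rose and 12 fell in EB. These counts were 62 and 5 in EC and 21 and 19 in EB after median ratio scaling, and 32 and 28 in EC and 25 and 18 in EB after quantile normalization. The times also differed in library sums and spread between replicates. The 12 h titles carry a group number, different for each agent, that the 24 h titles lack, and whether it marks a batch is not known here. The labels name no batch or date, so time and any batch cannot be told apart.

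**Figure D4:**
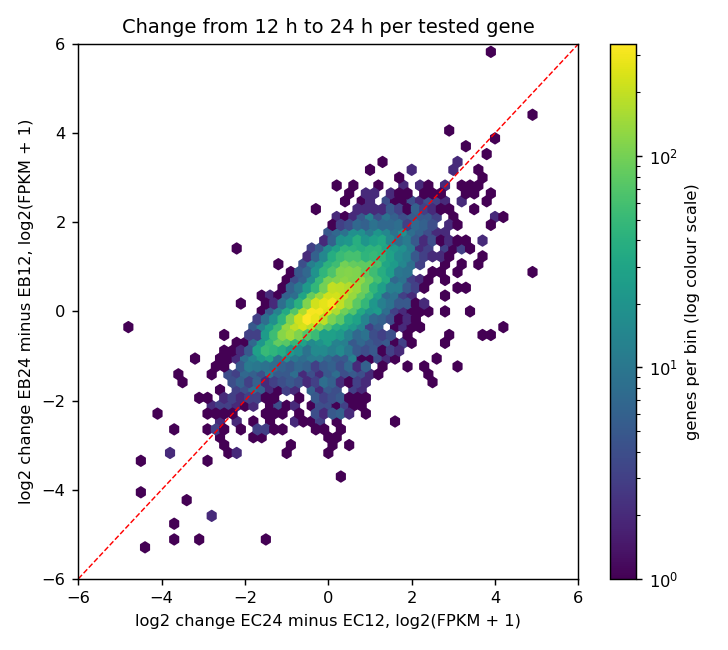
Change from 12 h to 24 h per tested gene in the EC libraries (x axis) and in the EB libraries (y axis), in log2(FPKM + 1) units, with colour for the number of genes per bin on a log scale and a dashed line of equal change. The cloud follows the line with r = 0.70 across 13768 genes.

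EB24 stood nearer to the 12 h libraries than EC24 did. The mean correlation of a library with the 6 libraries at 12 h was 0.927 ± 0.003 in EB24 and 0.909 ± 0.001 in EC24 (SD, n = 3), and all 3 EB24 values lay above all 3 EC24 values (exact permutation test, two-sided, p = 0.1, the smallest that 3 against 3 allows). Of the 2651 genes called at 24 h, 2248 (84.8%) had EB24 on the side of EC24 where the 12 h mean lay, against 66.5% of all tested genes. In 1382 of them EB24 lay between the 12 h mean and EC24, as for BXY_0640100, and in 866 it lay beyond the 12 h mean. In 403 genes EB24 lay away from the 12 h mean, as for BXY_0182200, at 5.47 ± 4.40 FPKM in EC12 and 6.33 ± 3.25 in EB12. The share was 88.4% after median ratio scaling and 84.7% after quantile normalization. EC24 enters both sides of this count. With 1 EC24 library held out to mark its level against 12 h, and used neither for the agent difference nor for the calls, the share was 87.8% to 88.2% of calls and 64.9% to 65.3% of all tested genes. These lists held 1361, 1160 and 1127 calls without EC24 replicates 1, 2 and 3. They are shorter than the 2651, so their shares of calls are not directly comparable with 84.8%. With the agents exchanged, EC24 lay on the 12 h side of EB24 in 47.9% of the 2651 calls, 44.6% after median ratio scaling and 50.9% after quantile normalization. EB24 was nearer than EC24 to the 12 h mean in 73.3%, 77.3% and 70.7% of calls.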

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

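The depth comparison and the regrouping of the 12 h libraries with the 24 h groups kept were chosen after the results they bear on had been seen, and the other tests before.

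The agent effect differed between 12 h and 24 h for 1145 genes by the interaction test (limma adjusted p under 0.05). Agent labels permuted within each time gave as many genes in 4 of 100 splits, the real one included, and 4210 in the highest of the others. That share of 0.04 does not bear on a difference between the times, since the 3 other splits kept the 24 h groups whole and it mostly retests the 24 h difference. With the 24 h groups kept, 8 of the 20 ways to regroup the 12 h libraries gave at least 1145 genes, the highest other being 4210, so chance in how the 12 h libraries are grouped is not excluded. A split with several times the real count points to a structure of the samples. Among the named genes that passed the interaction test, the 24 h effect minus the 12 h effect was -2.53 log2 units for BXY_0293300, -1.95 for BXY_1144700, 0.75 for BXY_0984700, 4.38 for BXY_0356800, 2.24 for BXY_0182200, 1.83 for BXY_0640100, -2.47 for BXY_0452800 and -2.46 for BXY_0214200. The other named genes did not pass it. They stood at -4.40 for BXY_1484600, -4.22 for BXY_0827600 and 0.82 for BXY_0200700 (limma adjusted p = 0.112, 0.102 and 0.0769). These genes were chosen for a large effect at 12 h, at 24 h or in the interaction, so their values are no separate evidence that effects differ between the times.

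The 12 h libraries were 2.43 times as variable as the 24 h libraries (ratio of median SDs) and did not sort by agent. Of the 10 splits of the 6 libraries, 4 gave at least the real 16 genes. The split that exchanges EC12 replicate 1 and EB12 replicate 2 gave 1974, which points to a structure of these samples other than the labels. These counts come from the 12-library fit, in which the tighter 24 h libraries lower the spread. No count from the 12 h libraries alone is given for that split, so its size is uncertain. Lower depth at 12 h is argued against, since the depth ratio of 12 h to 24 h libraries was 0.94 with the lower readings at 12 h, and 1.84 with the best ones, while counting noise would need 0.169, and counting noise of low genes is argued against by a ratio of SDs of 2.90 among genes with a mean FPKM of at least 50. Libraries caught at different points of the change from 12 h to 24 h are argued against along the first axis of the 12 h deviations. This axis held 54.7% of their variance and correlated with the mean of that change over both agents at only 0.085 in size. The value was 0.18 with the change in EC and -0.03 with that in EB, and the rest of the deviations was not compared. An exchange of 1 library between the groups could explain the split, but the contrast after such an exchange correlated with the 24 h effect at -0.19, and since the agent need not act alike at both times this leaves it open. No biological explanation was tested, because the design names no factor that divides the 12 h libraries.

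More genes were higher than lower with EB at 24 h, 75.4% of calls with the FPKM as deposited. The share was 57.4% after median ratio scaling, but centring lowers it with or without a true excess, so scaling of the deposited FPKM and an effect of the agent on more genes in one direction cannot be told apart. A few abundant genes taking more of the EC24 libraries are argued against as the only source, for the 100 most abundant genes. Without them and with equal totals the median difference was 0.12 log2 units, against 0.14 for all genes as deposited. These values differ in totals as well as in genes, so the part due to these 100 genes is not known. Abundant genes beyond these 100 were not left out.

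Splits of 3 against 3 are too few for a share under 0.05. For EB24 against EC24, EC24 against EC12 and EB24 against EB12, 1 of 10 splits, the real one, gave as many genes (2651, 6955 and 5975), the highest other being 0, and for EB12 against EC12 the real 16 stood against 1974.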

How the results depend on the processing

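The weights per time point, the fits of the 24 h libraries with 1 left out and the omission of 2 libraries at 12 h were chosen after seeing the data. No named gene reversed its sign in any setting among those run: 211 gene values kept their side of the threshold and 22 lost it. The genes named for an agent comparison had no overlap between its groups, so leaving out a library could not reverse them. All were chosen as called, and several settings leave the log2 difference itself unchanged, so these counts are weak evidence of stability. Of the counts, 69 stayed within 1.5 times the main value and 59 did not. The 16 genes of EB12 against EC12 became 0 with the compared groups alone, 5 with the replicate block, 1221 with library weights, 2 with weights per time point, 10 with at least 1 log2 unit of change, 1820 without EC12 replicate 1 and EB12 replicate 2, and 4 to 310 on leaving out 1 library. The 2651 genes of EB24 against EC24 became 7267 with the compared groups alone, 7997 with library weights, 7372 with weights per time point, 502 with at least 1 log2 unit, and 980 to 1361 on leaving out 1 library; in the 24 h libraries alone they were 6417, 6080 and 6218 without EB24 replicates 1, 2 and 3 and 7453, 6396 and 6469 without EC24 replicates 1, 2 and 3. With at least 1 log2 unit, EC24 against EC12 gave 2641 of its 6955 genes, EB24 against EB12 2412 of 5975 and the interaction 544 of 1145. Library weights gave 9628 genes for EB24 against EB12 and 5606 for the interaction. The interaction was 520 with median ratio scaling, 4574 without EC12 replicate 1 and EB12 replicate 2, and 177 to 2466 on leaving out 1 library. The 4 genes called in the same direction at both times became 0 with the compared groups alone, 2 with the replicate block, 256 with library weights, 2 with at least 1 log2 unit, and 1 to 51 on leaving out 1 library. The minimum change lowers counts by construction. The higher counts of EB24 against EC24 with the compared groups alone or weights per time point rest on the smaller 24 h spread. The median SD there was 0.114 log2 units, against 0.278 at 12 h. For the other moves the cause was not tested. The replicate block gave 2485, 6886, 5917 and 994 genes for the 24 h, EC, EB and interaction tests. The labels state no pairing by replicate number. Deviations from the group means correlated over 0.1 in 2 of 3 same-numbered pairs at 12 h (up to 0.343), 0 of 3 at 24 h (up to 0.041) and 2 of all 18. Differently numbered pairs of EB12 with EC12 ranged from -0.567 to 0.529, so the 0.343 does not stand out. By this measure 6 of 12 libraries matched best with their own number, where chance gives 4. With so few libraries these values leave a pairing open. Alternatives for gene lists, none of which was filled, were not run, nor the compared groups alone for the interaction, which uses all groups. Read totals are unknown, so no depth limit is given.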

Other observations

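The count with 1 EC24 library held out, the value for equal distances, the share of nearer genes and the share of signs in random orders were added after seeing the data. Few genes went from near silence to clear expression with the agent. Taking a mean FPKM under 1 in one group and at least 5 in the other, 2 genes were near silent in EB24 and present in EC24, both called, and 0 the other way. At 12 h, 1 gene was near silent in EC12 and present in EB12, not called, and 0 the other way. Over time such genes were more numerous: 23 appeared in EC (22 called) and 32 disappeared (26 called), and 30 appeared in EB (30 called) and 31 disappeared (25 called).

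EB24 lay nearer than EC24 to the 12 h libraries. With no library on both sides, the 24 h effect of EB and the change from 12 h to EC24 correlated across genes at -0.47 to -0.49 from EC12 and at -0.42 to -0.43 from EB12, the highest being -0.416. With EB24 and EC24 equally far from 12 h the value would be -0.29 to -0.30, and the rest restates that EB24 lay nearer, so whether EB held back a change that control worms went through was not tested. After quantile normalization 84.7% of the 24 h calls had EB24 on the 12 h side of EC24, against 67.4% of all tested genes. With 1 EC24 library held out from the difference and the calls, these shares were 85.8% to 88.2% and 64.4% to 66.7%. They cannot decide on scaling, since such a share is high even with EB24 and EC24 equally far from 12 h. With the agents exchanged, EC24 lay on the 12 h side of EB24 in 50.9% of these calls. EB24 was the nearer in 70.7%, which argues against scaling as the only source. The proportion of sexes or stages among the 200 worms of each library, which may also differ, was not tested, and a difference between the 12 h and 24 h libraries in handling would enter the time change in both agents.

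Genes with adjacent BXY numbers tended to change together at 24 h. Over 11151 adjacent pairs the log2 differences correlated at 0.104, above the highest of 100 random orders (0.024), and 57.0% of pairs shared a sign, against a mean of 54.0% and at most 55.2% in the random orders. Whether adjacent numbers are neighbours in the genome was not checked.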
